A study of Mus musculus with 6 samples.

How the data were processed

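The series measured the transcriptomes of sorted mouse myeloid cells by RNA sequencing, in 6 libraries. Per the labels, the cells were monocytes, intravascular macrophages or microglia, and came from wild-type mice or from mice carrying the BRAF V600E mutation. Each combination of cell type and genotype was 1 library. The labels' protocols give column extraction of total RNA with the RNeasy Plus Mini kit, full-length cDNA made with the SMART-Seq HT kit for very low input, and sequencing libraries made with Nextera XT. The labels do not say how many animals or cells went into a library, whether the 3 cell types of a genotype came from the same mice, or how the cells were gated.

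The authors deposited a table of raw read counts per gene and a table of TPM, in which counts are divided by gene length and scaled to the same sum per library, for the same 6 libraries, per the file headers. Per the submitters' processing notes, the tools named were bcl2fastq 2.20, Trimmomatic 0.37, STAR 2.5.2b and Subread 1.5.2, with the mouse build mm10. Their roles, the gene annotation and the use of strand are not given in the sources used here. The deposited count table had 49315 lines. Of these, 176 had no gene name and were left out of library sizes and of every test; they held between 0.00507% and 0.0166% of a library's counts. A further 26 lines carried a date in place of a symbol, with 0.0618% to 0.237% of the counts, and were left out as well. The 94 symbols found on more than 1 line were summed, which left 49016 gene symbols. In the deposited TPM table the ratio of count to TPM of a gene was constant across libraries up to 1 factor per library, so both tables hold the same reads. The predicted gene Gm23935, chosen after its values were seen, took 46.6% of the TPM of wild-type intravascular macrophages and 38.1% of that of wild-type microglia, against 5.02% and 1.13% in the mutant libraries of those cells, so counts were used throughout and TPM only as an alternative.

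Total counts per library ran from 25787476 to 65519506. Counts were scaled by edgeR 4.0.16 in R 4.3.3 with TMM factors and are given as CPM, counts scaled to a common library size. With 1 library per genotype in each cell type, no difference between genotypes has a replicate check and no p-value was computed for it; cell types were not used as replicates of a genotype. The log2 ratio of mutant to wild type was computed with a prior count of 2. A gene passed the size rule when its absolute log2 ratio was at least 2, that is 4-fold, and it reached 10 CPM in the higher library. Folds of single genes carry exact conditional binomial 95% intervals of the counts of the 2 libraries. Reads amplified by PCR and counted without molecular identifiers are not independent molecules, so these intervals and the floors cover counting error only. Where a library held 0 counts of a gene, the fold is a bound against a floor of 3 counts per library, written as at least; with 1 to 3 counts the ratio and its interval are given.

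For 37 gene lists (markers of blood and brain cell types, and pathways), the median log2 ratio of the members with a mean of at least 1 CPM was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list with at least 3 such members was said to stand apart when its median lay below percentile 2.5 or above percentile 97.5 of the random lists, which describes these libraries and is no test of genotype. Cell types were compared with edgeR's quasi-likelihood test on all 6 libraries, with genotype as a block, filterByExpr by cell type and Benjamini-Hochberg adjustment at 0.05. This leaves 2 residual degrees of freedom. A difference between genotypes that is not the same in each cell type counts as spread in this fit. Nothing beyond the genotype says that libraries of a cell type came from separate animals, so p-values measure only the spread between these libraries, part of which may be technical. For each list, members past the test were counted over all genes and adjusted over the list alone.

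The groups, the lists, the size rule, the tests, most of the alternatives and the rule for named genes were fixed before the data were examined. That rule takes, in each cell type, the 10 genes with the largest positive and the 10 with the largest negative log2 ratio among those past the size rule, without predicted genes, pseudogenes and genes of ribosomal proteins, mitochondria, immunoglobulins or T cell receptor segments. It adds up to 4 members of each list that reach 10 CPM and a 2-fold ratio, genes past the size rule in the same direction in all 3 cell types, and the 10 largest fold changes per direction of each cell type comparison that go the same way in both genotypes with 10 CPM in both libraries of the higher cell type. Braf, Cdkn1a, Cdkn2a and the microglia and monocyte markers were named in any case. Genes named outside it are said to be chosen after their values were seen. Coordinates, transcript lengths and GC contents come from GENCODE release M21 on mm10; 99.2% of the symbols at 10 CPM or more in a library had a length and a GC content. Members of gene families that share near-identical reads (Stfa, Hba and Hbb, Ifit3 and Ifit3b, Bcl2a1, H2, Igkc and Igh genes, Ly6c), overlapping genes and antisense genes are uncertain, since the counting of shared reads and of strand is not known.

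The test of cell types was run on simulated negative binomial counts with 200 changed genes. At a dispersion of 0.1 it recovered 78 of 100 genes changed by 4-fold and 100 of 100 changed by 16-fold for intravascular macrophages against monocytes (16572 genes). For intravascular macrophages against microglia it recovered 77 and 100 of 100 (16572 genes), and for microglia against monocytes 69 and 100 of 100 (16489 genes), with 5, 5 and 6 false calls in the same order. At a dispersion of 0.8, near the common dispersion of 0.851 estimated from the real libraries, it recovered 0 of 100 at either fold in each of the 3 comparisons, with 0 false calls. The size rule was run for monocytes on counts simulated with counting error only, without spread between libraries. It recovered 195 of 200 genes changed by 8-fold among 16710 simulated genes, and 95.3% of unchanged genes had an interval that held the true ratio. This checks the computation. It does not show how often unchanged genes pass the rule at the spread of the real libraries.

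Alternatives for the genotype ratios were DESeq2 1.42.0 size factors, library size alone, other minimum levels, prior counts and ratio thresholds, and log2(TPM + 1). For the cell types they were DESeq2's Wald test, DESeq2 size factors, no filter on low counts, no genotype block, only the 4 libraries compared, a fold threshold, limma 3.58.1 on log2(TPM + 1) and leaving out each library. A correction of log2 ratios for their trend with transcript length and GC content, random lists matched on mean expression and transcript length, overlaps expected within bins of transcript length, thinning to equal depth, leaving out the intravascular macrophages, leaving out genes missing from or specific to their wild-type library, and counts of list members past the cell type tests were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.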

Results

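RNA of 3 kinds of sorted mouse myeloid cell was sequenced: monocytes, which circulate in blood and enter tissues, intravascular macrophages, which lie within vessels, and microglia, the resident macrophages of the brain. Each was taken from wild-type mice and from mice with BRAF V600E, a substitution that keeps the BRAF kinase active and with it the MEK and ERK kinases. The 6 groups held 1 library each. Total counts were 25787476 in wild-type and 62110213 in mutant monocytes, 29000457 and 65519506 in wild-type and mutant intravascular macrophages, and 35418646 and 38852081 in wild-type and mutant microglia. A count was found for 15121 genes in wild-type intravascular macrophages, the fewest, and for 23214 in mutant intravascular macrophages, the most. The other libraries held 19063 (wild-type monocytes), 20486 (mutant monocytes), 21880 (wild-type microglia) and 20321 (mutant microglia). The questions were how the mutant cells differ from wild-type cells of the same type, and how the 3 cell types differ from each other.

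Braf itself (ENSMUSG00000002413.15, protein coding, chromosome 6, 39603237 to 39725463, minus strand, build mm10, GENCODE M21) was read in all 6 libraries. It stood at 27.0 CPM in wild-type and 13.3 CPM in mutant monocytes, 2.03-fold lower (95% counting interval 1.80 to 2.28). Intravascular macrophages had 44.1 CPM in wild type and 26.0 in the mutant, 1.70-fold lower (1.59 to 1.81), a direction that turned with TPM (log2 ratio 0.38). In microglia it was 51.8 CPM against 7.22, 7.18-fold lower (6.28 to 8.24). The log2 ratio of -2.84 in microglia became -1.96, short of the size rule, after correction for transcript length and GC content. Gene counts do not show which allele was read, so they do not check the mutation.

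Marker genes of microglia and classical monocytes were strongest where the labels place them, and genes of other blood cells were read as well. Microglia markers such as P2ry12, Tmem119 and Sall1 summed highest in both microglia libraries, and classical monocyte markers in both monocyte libraries. Patrolling monocyte markers summed to 3631 and 4587 CPM in wild-type and mutant intravascular macrophages and to 2507 and 2419.5 CPM in monocytes; no list was held for intravascular macrophages themselves. T and NK cell markers summed to 5195.5 CPM in wild-type intravascular macrophages, where 14 of 14 genes reached 10 CPM, and to 3.57 CPM in the mutant ones. Neutrophil markers summed to 58105 CPM in mutant and 2397 CPM in wild-type monocytes, and erythroid markers to 10500 and 227 CPM. Across 8705 genes, the Spearman correlation of wild-type with mutant libraries was 0.865 for monocytes, 0.739 for microglia and 0.553 for intravascular macrophages. Mutant intravascular macrophages correlated more closely with every other library than with their own wild type. The values were 0.735 for wild-type and 0.686 for mutant microglia, and 0.632 for wild-type and 0.604 for mutant monocytes. Wild-type intravascular macrophages lay between 0.41 and 0.534 with the monocyte and microglia libraries. Genes are not independent replicates.

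**Figure D1:**
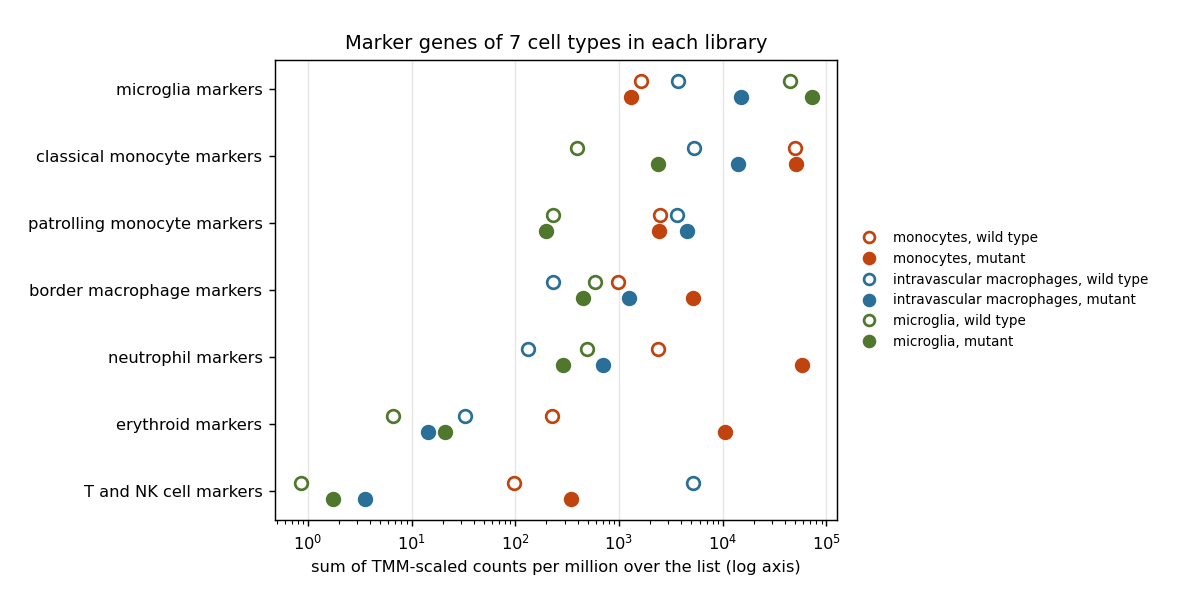
Sum of TMM-scaled CPM (log axis) over 7 lists of marker genes, each point 1 library, open for wild type and filled for mutant. T and NK cell markers stand at 5195.5 CPM in wild-type intravascular macrophages, and neutrophil markers at 58105 CPM in mutant monocytes.

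Mutant monocytes were first set against wild-type monocytes. The largest differences were genes higher in the mutant library. Retnla, a secreted protein of alternatively activated macrophages (chromosome 16, 48842551 to 48844461, plus strand), had 352 CPM in the mutant and 0 in the wild type, at least 2767-fold higher. Arg1, the arginase of the same activation state, was at 332 CPM against 0.0424 (7829-fold, 1405 to 309242, on 1 wild-type count). Spp1, the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050, plus strand), was at 2639.5 CPM against 0.974, 2709.6-fold higher (1806 to 4275). The chemokines that draw in neutrophils and monocytes stood beside them. Cxcl2 (chromosome 5, 90903871 to 90905938, plus strand) was 3669-fold higher (2051 to 7351), Ccl7 1979-fold (1218 to 3462) and Cxcl1 7064-fold (1268 to 279028, on 1 wild-type count).

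The other genes of this rank in monocytes belong to granulocytes. Stfa2l1 and Stfa2, stefin A protease inhibitors of neutrophils, were at least 1678-fold and at least 1187-fold higher, and Stfa1 2495-fold (853 to 12099, on 3 wild-type counts). Prg2, the major basic protein of eosinophils, was 2971-fold higher (822 to 24532, on 2 wild-type counts). Genes lower in mutant monocytes differed far less. The largest were AA474408 at 29.9-fold lower (17.5 to 55.4), Slc14a1 at 12.01-fold, Zfp101 at 11.2-fold and Epha1 at 9.56-fold. Ifit3b, an interferon-induced gene, was 9.32-fold lower (7.56 to 11.6). S1pr5, a sphingosine phosphate receptor (chromosome 9, 21242912 to 21248443, minus strand), was 9.13-fold lower (7.77 to 10.8), and Irf4, a transcription factor of dendritic cells and lymphocytes, 7.46-fold (6.46 to 8.65). Plxdc1, Dyrk3 and Klf11 were 6.97-fold, 6.34-fold and 6.22-fold lower.

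Of the 35 lists with enough measured members in monocytes, 20 stood apart as higher in the mutant (percentiles of 98.1 to 100 among random lists). Another 3 stood apart as lower (0.15 to 0.98). Independent lists of independent genes would give 0.875 per side. The lists share members, such as Spp1 and Mmp9, so the 20 are not separate results and that value is no test. The secretory factors of senescent cells had a median log2 ratio of 3.28, with 31 of 41 members at least 2-fold higher. After the chemokines, they included Cxcl3, at least 555-fold higher, and Timp1, an inhibitor of metalloproteinases, at 1767-fold (317 to 69825, on 1 wild-type count). Metalloproteinases and their inhibitors had a median of 3.52 (11 of 17 higher): Mmp9 was 750.1-fold higher (419 to 1503) and Adam8 15.8-fold, while Adam19 was 5.33-fold lower. Mmp8 and Mmp9 are also on the list of neutrophil markers, which stood higher in this library too. Targets of the ERK pathway had a median of 2.37, with 15 of 19 higher, among them Ier3 (38.4-fold, 31.5 to 47.3) and Etv5 (19.8-fold, 13.97 to 29.2). Cdkn1a, the cell cycle inhibitor p21 (chromosome 17, 29090976 to 29100727, plus strand), was 13.6-fold higher in mutant monocytes (12.9 to 14.3). The senescence list as a whole had a median of 0.41 and did not stand apart. Cdkn2a had at most 15 counts in any of the 6 libraries and gave no ratio.

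Macrophage genes were higher in mutant monocytes. Markers of border macrophages, the macrophages of meninges and perivascular spaces, had a median of 3.31, with 11 of 12 at least 2-fold higher. Folr2 was at least 83.7-fold higher, Stab1 198-fold (125 to 335) and Pf4, which platelets also make, 130.04-fold (116 to 146). Complement genes had a median of 1.85, led by C1qb (94.1-fold, 81.7 to 109) and C3ar1 (70.8-fold). Genes of disease-associated microglia (2.19) included Cd63 at 35.3-fold and the protease Ctsl at 17.0-fold. Scavenger and efferocytosis receptors (1.69) included Mertk at 32.5-fold (20.2 to 56.1). The list of Langerhans cell histiocytosis genes, a disease in which BRAF V600E is common, had a median of 2.03 with 10 of 15 higher. Cell cycle genes had a median of 1.53, with 29 of 39 higher, such as Ube2c (24.2-fold, 15.7 to 39.3), Stmn1 (18.0-fold) and Top2a (11.1-fold).

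Smaller shifts were found in NF-kB and inflammatory genes (0.91), glycolysis and hypoxia genes (0.98, with Ankrd37 at 30.8-fold and Vegfa at 18.2-fold), unfolded protein response genes (1.04, with Manf at 10.4-fold), and lysosome and lipid handling genes (0.75). Dendritic cell markers stood lower at -0.93: Dpp4 was 4.03-fold lower (3.55 to 4.57) and Cd209a 3.12-fold (2.92 to 3.35). Type I interferon response genes had a median of -0.40, with Ifit3 4.23-fold lower and Isg15 4.14-fold higher. Immediate early genes, which are switched on within minutes of a stimulus, had a median of -0.26, with Atf3 3.70-fold and Fosb 3.55-fold lower. Monocyte markers themselves did not stand apart: the classical list had a median of 0.55, the patrolling list -0.19, with Ly6c2 2.31-fold higher (2.28 to 2.35) and Ace 2.77-fold lower (2.63 to 2.91). The patrolling list did stand apart as lower after correction for transcript length and GC content (median -0.66, percentile 0.13) and on TPM, but not against random lists matched on transcript length (percentile 6.17).

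Genes of other blood cells moved with these groups in mutant monocytes. Neutrophil markers had a median of 4.51, with 12 of 14 at least 2-fold higher, led by Retnlg at 1446-fold (1180.4 to 1792) and S100a8 at 37.9-fold (37.3 to 38.6). Immature granulocyte and stem cell markers stood at 3.88 (Ms4a3 42.0-fold, Prtn3 17.0-fold, Elane 16.2-fold). Erythroid markers stood at 5.65, or 5.50 with genes at 0 counts at their bound: Hba-a1 was 58.3-fold higher (55.7 to 61.1). Platelet markers (2.95, Ppbp at 17.0-fold), B cell markers (2.49, Cd79a at 27.6-fold, 16.9 to 48.6), T and NK cell markers (1.79, Cd3g at 13.2-fold, 8.33 to 22.1) and astrocyte markers (2.05, on 4 measured genes) were higher as well.

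By the size rule, 534 genes were higher and 51 lower in mutant monocytes, of 8377 genes at 10 CPM or more in a library. Scaling by library size alone, which moved the median of all genes from 0.05 to -0.54, gave 242 higher and 184 lower, TPM gave 166 and 169, and the correction for transcript length and GC content 358 and 93. On TPM, the medians of the NF-kB, lysosome and unfolded protein response lists turned to -0.10, -0.11 and -0.16, and the immediate early genes no longer stood apart after correction for transcript length and GC content (percentile 10.5), though they did against random lists matched on transcript length (0.665). The T and NK cell, B cell, astrocyte and lysosome lists no longer stood apart with a mean of at least 10 CPM required. On TPM the astrocyte and unfolded protein response lists no longer did, while the NF-kB and lysosome lists kept their side against random lists. Isg15 missed the size rule after the correction for length and GC content, at 0.83.

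**Figure D2:**
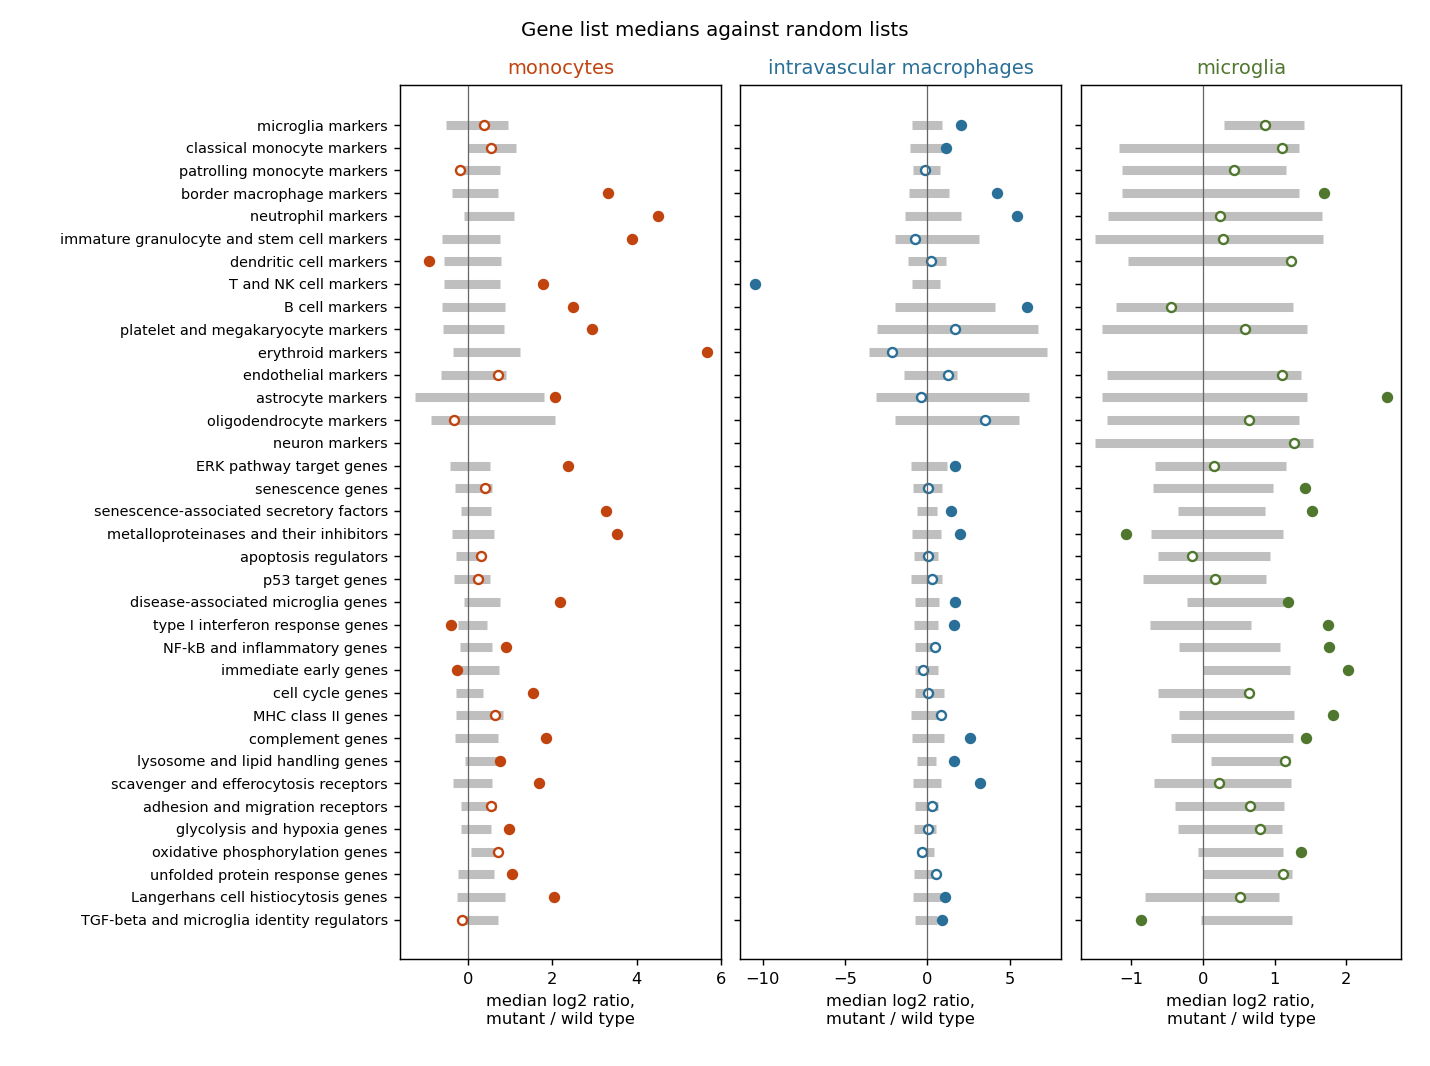
Median log2 ratio of mutant to wild type (x axis) for each list (y axis) in 3 panels, 1 per cell type; grey bars hold 95% of random lists and filled points stand apart from them. The T and NK cell list stands at -10.46 in intravascular macrophages, and 11 lists stand apart as higher in microglia.

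The comparison of mutant with wild-type intravascular macrophages gave the largest differences. Genes of macrophages were higher and genes of T and NK cells lower in the mutant library. Axl, a receptor for the uptake of dying cells (chromosome 7, 25757273 to 25788705, minus strand), was at 412 CPM against 0.191, 2157-fold higher (1047 to 5366). Nr1h3, the sterol sensor LXR alpha, was at 78.4 CPM against 0 counts, at least 957-fold higher. Fpr1, a receptor for formyl peptides of bacteria (chromosome 17, 17876471 to 17883940, minus strand), was 4632-fold higher (1282 to 38252, on 2 wild-type counts), and Mmp12, the macrophage elastase, 3416-fold (946 to 28211, on 2 counts).

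Retnla was 1701-fold higher in these cells too (582 to 8251, on 3 wild-type counts). The interferon-induced genes Oas2 and Oasl2 were 2549.7-fold (457 to 100725, on 1 count) and 1978-fold higher (548 to 16339, on 2 counts). Fcrl5, Emilin1 and St7, all at 0 wild-type counts, were at least 585-fold, 554-fold and 467-fold higher. The wild-type library held the fewest genes with a count (15121) and lacked genes read in all other libraries, as given below. Folds on few wild-type counts in this comparison, such as 3 or fewer or the 7 of Axl, may therefore reflect lost transcripts. This was not tested gene by gene. In the other direction, Cd8a (chromosome 6, 71373427 to 71379173, plus strand), a chain of the T cell coreceptor, had 242 CPM in wild type and 0 counts in the mutant, at least 6885-fold lower. Cd163l1, a scavenger receptor family gene, went from 501 to 0.0351 CPM (14262-fold lower, 4879.6 to 69166, on 3 mutant counts). Cxcr6, a chemokine receptor of T and NKT cells, was 4228-fold lower (2675 to 7135), Nkg7, a cytotoxic granule gene, 2907-fold (2126 to 4089), and Cd3d, part of the T cell receptor complex, 4023-fold (2119 to 8800). Thy1, Il2rb, Cd8b1, Gzmb and Cd3g were between 2568-fold and 5376-fold lower.

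T and NK cell markers were the only list standing apart as lower in mutant intravascular macrophages, with a median of -10.46 over 14 of 14 members, below all random lists. The 15 lists standing apart as higher lay at percentiles of 99.0 or more. Whether reads from T or NK cells in the wild-type library lowered its share of macrophage reads, and so raised these lists, was not tested. Microglia markers had a median of 2.01, with 13 of 14 at least 2-fold higher, such as P2ry13 (5.94-fold, 5.72 to 6.17) and Csf1r (5.15-fold, 5.10 to 5.21). Border macrophage markers had a median of 4.24: Cbr2 was at least 202-fold higher, Ms4a7 397-fold (155 to 1459) and Mrc1, the mannose receptor, 171-fold (125.5 to 239). Classical monocyte markers (1.13) included the matrix and clotting genes Fn1 at 458-fold (299.5 to 740.0) and F13a1 at 394-fold (255 to 646). Neutrophil markers (5.45, Mmp8 at 373-fold) and B cell markers (6.04, with Cd22 655-fold higher and Ms4a1 555-fold lower on 2 mutant counts) stood among them.

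Scavenger and efferocytosis receptors in these macrophages had a median of 3.21, with Msr1 at 864-fold (455 to 1890) and Gas6, the ligand of Axl, at 285-fold, while Tyro3 was at least 1078-fold lower. Complement genes (2.60) included C5ar2 at no wild-type counts, at least 364-fold higher, and C3ar1 at 568-fold (355 to 976). Genes of disease-associated microglia (1.67) included Lpl at 410.1-fold (229 to 822) and Clec7a at 147.5-fold. Interferon response genes (1.64, 17 of 29 higher) included Ifit1, at least 263-fold higher, and Rsad2 (295-fold, on 3 wild-type counts). Lysosome and lipid handling genes stood at 1.59 (Abca1 7.47-fold), metalloproteinases at 1.96 (Adam9 320.2-fold), senescence-associated secretory factors at 1.43 (Ccl8 at least 464-fold) and Langerhans cell histiocytosis genes at 1.05.

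ERK target genes in intravascular macrophages went both ways around a median of 1.69: Spry4, a feedback inhibitor of the pathway, was at least 179-fold and Etv5 11.3-fold higher (10.3 to 12.5), while Spry2 was 78.4-fold (43.3 to 158) and Dusp4 30.7-fold lower. TGF-beta and microglia identity regulators stood at 0.87, with Tgfbr1 13.7-fold higher and Cebpb 43.8-fold lower (40.9 to 47.1). The senescence list had a median of 0.02, and Cdkn1a a log2 ratio of -0.56. Cell cycle (0.05), apoptosis (0.03), glycolysis (0.06), oxidative phosphorylation (-0.30), NF-kB (0.43) and immediate early genes (-0.28) lay inside the random range.

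In all, 1579 genes were higher and 1256 lower by the size rule, of 9565, and 44.2% of genes lay within 2-fold, against 77.0% in monocytes and 46.7% in microglia. TPM gave 2514 higher and 493 lower, and the correction for length and GC content turned the majority, with 1335 higher and 1510.0 lower. A set of 72 genes reached 10 CPM in each of the other 5 libraries and had at most 3 counts in the wild-type one. No other library lacked any gene in this way. A wider filter dropped every gene with at most 3 wild-type counts, whatever its level elsewhere. It also dropped genes at least 10 times above the mean of the other libraries there. With it, 1193 genes were higher and 804 lower. The B cell list no longer stood apart with library size alone, the ERK list on TPM, and the TGF-beta list after correction for length and GC content (percentile 96.2, though 99.8 against random lists matched on length). The correction also took Csf1r below the size rule, to 1.84.

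The single genes furthest above wild type in mutant microglia included some of stress and inflammation. Atf3, a stress-induced transcription factor (chromosome 1, 191170296 to 191218039, minus strand), was at 5418 CPM against 81.2, 66.7-fold higher (64.6 to 68.9). Il1b, which encodes interleukin 1 beta (chromosome 2, 129364570 to 129371139, minus strand), was 61.0-fold higher (54.3 to 68.7), Gadd45b, a stress sensor, 50.04-fold (44.2 to 56.9) and Cxcl2 74.8-fold (53.6 to 108). Ttr and Ccl8 were 913-fold (163 to 36120) and 573-fold higher (102 to 22693), each on 1 wild-type count. The protease Ctsk and the phosphatase Acp5, both known from osteoclasts, were 227-fold (88.3 to 836) and 71.3-fold higher (37.2 to 157), Sirpb1c 58.7-fold and Tnfsf9 42.1-fold.

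Among genes lower in mutant microglia, Ano8 stood at 0.338 CPM against 20.1, 59.5-fold lower (33.1 to 120), followed by Mfsd4a at 53.6-fold, Scube1 at 35.9-fold, Kcnk12 at 26.2-fold and Gsk3a at 25.4-fold. Upf1, the helicase of nonsense-mediated decay, was 17.1-fold (14.8 to 19.98), Mir6236 13.1-fold, Dagla 12.5-fold, the corepressor Ctbp1 12.03-fold and Cebpb, a transcription factor of myeloid cells, 10.6-fold lower (9.34 to 12.1). Of these, Dagla missed the size rule after correction for length and GC content, at -1.95. Microglia markers did not stand apart as a list (median 0.86): Olfml3 was 2.51-fold higher (2.48 to 2.53) while Csf1r, the receptor microglia need to survive, was 3.21-fold lower (3.19 to 3.23), at a corrected log2 ratio of -0.66.

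Of 34 lists ranked in microglia, 11 stood apart as higher (percentiles above 98.5) and 2 as lower (0.4 and 0.01). Independent lists of independent genes would give 0.85 per side, but the lists share members. Immediate early genes had a median of 2.03, with 15 of 22 at least 2-fold higher; Fos was 22.1-fold (21.8 to 22.3), Ier3 15.7-fold and Dusp1 13.4-fold higher. NF-kB and inflammatory genes had a median of 1.75, with 17 of 24 higher, such as Nfkbia, the inhibitor that NF-kB induces, at 23.2-fold (22.8 to 23.7) and Ptgs2 at 18.2-fold (12.3 to 28.0). Senescence genes (1.43, 11 of 21 higher) included Gdf15 at 21.8-fold (18.8 to 25.5) and Hmgb1 at 4.04-fold, and Cdkn1a was 3.66-fold higher (3.34 to 4.02). Secretory factors of senescent cells (1.52, 26 of 39 higher) included Ccl4 at 17.4-fold (17.1 to 17.6).

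MHC class II genes, which present antigen, had a median of 1.82 in microglia, with 12 of 14 higher: H2-Eb1 was 9.17-fold (8.74 to 9.62) and H2-Aa 8.39-fold higher. Interferon response genes (1.74, 19 of 28 higher) included Cxcl10 at 7.65-fold (6.79 to 8.64) and Ifitm3 at 7.30-fold. Oxidative phosphorylation genes had a median of 1.37, with 27 of 30 higher, led by Sdhc at 6.89-fold and Sdhd at 3.82-fold. Complement genes (1.43) included C5ar1 at 4.25-fold. Genes of disease-associated microglia (1.18) included Spp1 at 10.4-fold (8.25 to 13.3) and Apoe, a lipid carrier, at 7.70-fold. Border macrophage markers (1.68, Ms4a7 at 14.4-fold) and astrocyte markers (2.56, on 4 measured genes, Aldoc at 11.7-fold) stood apart too. Metalloproteinases were lower, at -1.08, with Timp2 5.09-fold (4.91 to 5.28) and Adam10 4.42-fold lower, and so were TGF-beta and microglia identity regulators, at -0.87, with Cebpb and Itgav (4.12-fold).

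ERK target genes did not stand apart in microglia (median 0.15). Nor did p53 targets (0.17; 0.23 in monocytes, 0.31 in intravascular macrophages), apoptosis regulators (-0.15; 0.32 in monocytes), adhesion and migration receptors (0.65; 0.54 in monocytes, 0.28 in intravascular macrophages) or endothelial markers (1.10; 0.72 and 1.25). Oligodendrocyte markers (0.64) and neuron markers (1.27) did not either, and mural and fibroblast markers had no more than 2 measured genes in any cell type and were not ranked. After correction for length and GC content, lists of this kind stood apart as higher: in microglia neuron markers (median 1.99, percentile 99.7, 4 of 4 at least 2-fold higher), p53 targets (0.62, percentile 98.9) and glycolysis and hypoxia genes (0.85, percentile 99.7), in monocytes apoptosis regulators (0.27, percentile 98.9) and adhesion and migration receptors (0.51, percentile 99.7), and in intravascular macrophages MHC class II genes (0.75, percentile 98.6). Against random lists matched on length, neuron markers (99.5), adhesion receptors (99.8) and MHC class II genes (98.8) stood apart as well, while p53 targets (44.5), glycolysis genes (80.8) and apoptosis regulators (85.85) did not. Neuron markers in microglia stood apart with DESeq2 size factors too.

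By the size rule 249 genes were higher and 408 lower in mutant microglia, of 8798. The ratio followed transcript length in these cells: its median was 1.31 in the bin of the shortest transcripts (median 1005 nt) and -0.96 in that of the longest (8159 nt), with a Spearman correlation across genes of -0.603, against -0.397 in monocytes and 0.188 in intravascular macrophages. After correction for length and GC content 221 genes were higher and 125 lower, and the lists of disease-associated microglia (percentile 62.8), oxidative phosphorylation (58.9) and TGF-beta genes (8.08, median turned to 0.090) no longer stood apart. Against random lists matched on transcript length the first and the last still did (98.2 and 0.98), and oxidative phosphorylation genes did not (97.35). With a mean of at least 10 CPM required, the border macrophage, astrocyte and disease-associated microglia lists did not stand apart, nor did the last of these on TPM. Of the list members named here, Ifitm3 (1.37), Hmgb1 (1.53), C5ar1 (1.71), Spp1 (1.83), Itgav (-1.23), Timp2 (-1.72) and Adam10 (-1.76) then missed the size rule. Library size alone, which moved the median of all genes from 0.12 to -0.50, gave 87 higher and 1437 lower, and TPM 153 and 384.

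**Figure D3:**
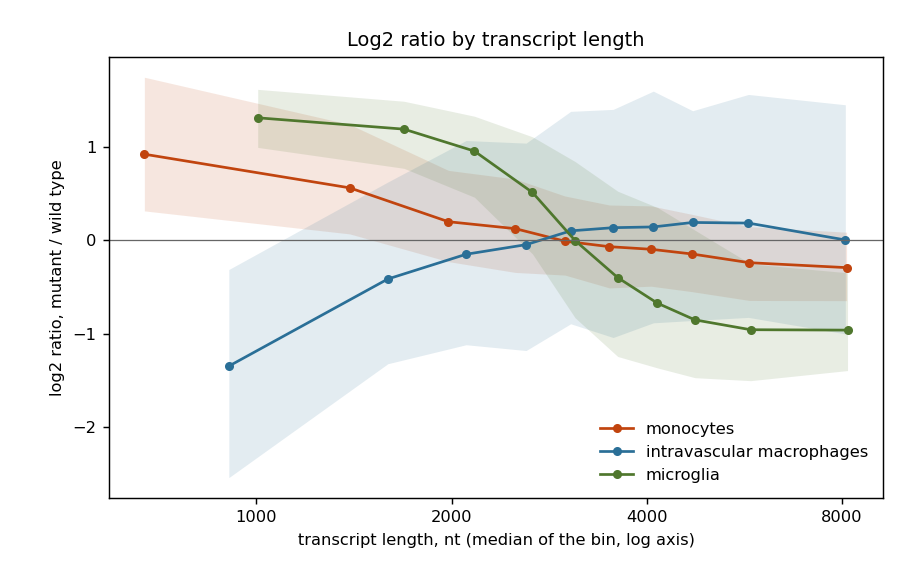
Log2 ratio of mutant to wild type (y axis) against transcript length in nt (log x axis), as medians of 10 bins of genes (points) with the 25th to 75th percentile shaded, 1 colour per cell type. The microglia median goes from 1.31 in the shortest bin to -0.96 in the longest.

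Genes that passed the size rule in all 3 cell types were all higher in the mutant. There were 17, against 1.22 for independent lists among the 6935 genes measured in all 3, and 0 lower genes, against 0.0313. They hold monocyte chemoattractants and receptors of inflammation. Spp1 was 2709.6-fold, 12.8-fold and 10.4-fold higher in monocytes, intravascular macrophages and microglia, in that order. Cxcl2 was 3669-fold, 46.0-fold and 74.8-fold higher, Ccl12 973-fold, 31.7-fold and 13.5-fold, and Ccl7 1979-fold, 8.05-fold and 6.80-fold. Gpr84, a receptor for fatty acids, was 10.9-fold, 9.99-fold and 6.89-fold higher, and Cd14, the lipopolysaccharide coreceptor, 7.60-fold, 7.42-fold and 5.59-fold.

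The same set of shared genes held the complement receptor C5ar1, the Fc receptor Fcgr4, the chemokine receptor Ccr1, the scavenger receptor Msr1 and the metallothionein Mt1, with Ccl8, Ms4a7, Cd300lf, Egr2, Ang and Scimp. Some had few counts in wild-type intravascular macrophages: Ccl8 0, Egr2 1, Scimp 3, Ms4a7 4, Ang 5, Ccr1 6 and Msr1 9. The rest had 29 or more. Calls on few counts there may reflect lost transcripts, which was not tested gene by gene. The direction was less uniform in other settings: 10 higher and 1 lower gene were shared after correction for length and GC content, 9 and 1 with library size alone, 49 and 3 at 1 CPM, and 116 and 28 at a log2 ratio of 1. Of the 17 genes, 8 kept their call after correction for length and GC content, 8 on TPM and 9 with library size alone. In pairs of cell types, monocytes and microglia shared 55 higher genes (8.14 for independent lists), monocytes and intravascular macrophages 70 (45.1), and intravascular macrophages and microglia 38 (27.9). Intravascular macrophages and microglia shared 67 lower genes (12.05), monocytes and microglia 3 (0.709) and monocytes and intravascular macrophages 0 (0.794). At a log2 ratio of 1, the higher genes shared by intravascular macrophages lay below the value for independent lists, at 227 with monocytes (264) and 422 with microglia (548), while monocytes and microglia shared 658 (284). The lower genes shared by intravascular macrophages and microglia were then 344 (333). Ratios fell with transcript length in both monocytes and microglia. For lists independent within 10 bins of transcript length, among 6882 genes with a length, the value for these cell types was 15.9 against 54 shared higher genes, and 464 against 652 at a log2 ratio of 1. The deficit of intravascular macrophages at a log2 ratio of 1 did not hold with monocytes within these bins, at 226 shared higher genes against 210. With microglia it was smaller, at 419 against 445.

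**Figure D4:**
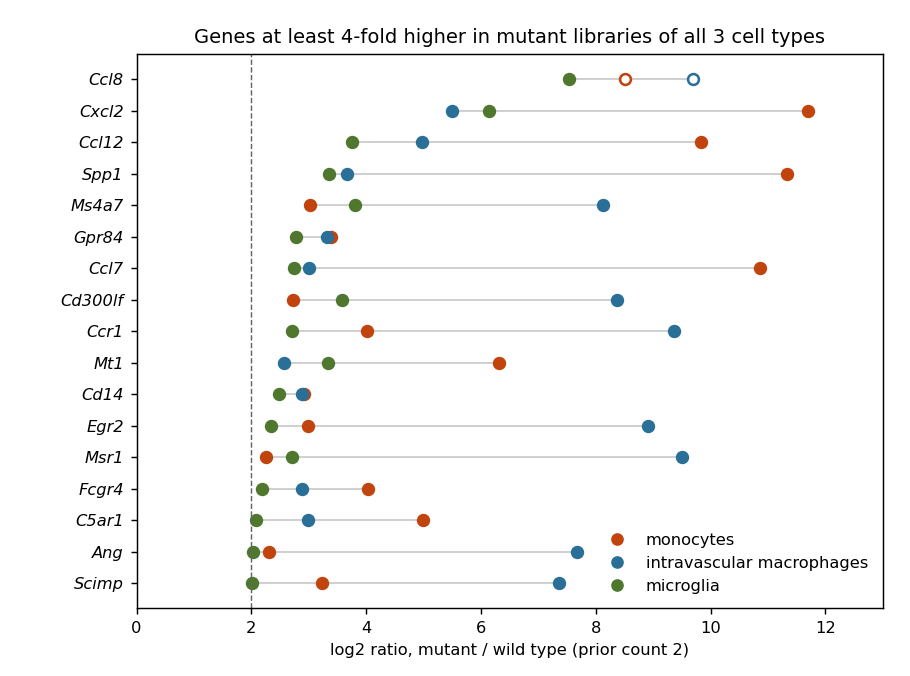
Log2 ratio of mutant to wild type (x axis, prior count 2) for the 17 genes (y axis) at least 4-fold higher in the mutant library of each cell type, 1 point per cell type, open where the wild type had 0 counts. The dashed line marks the threshold of 2; the log2 ratio of Cxcl2 in monocytes is 11.71.

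Some genes of microglia were higher in the intravascular macrophage libraries than in the monocyte libraries, and some genes of classical monocytes and neutrophils lower. The gate is not known, so whether the macrophages themselves or microglia in the sort gave the microglia genes was not tested. Sall1, a transcription factor of microglial identity (chromosome 8, 89027235 to 89044162, minus strand), was at 30.2 and 93.2 CPM in wild-type and mutant intravascular macrophages and at 0.0847 and 0.159 CPM in monocytes. Its log2 fold change was 8.82 (SE 1.10, adjusted p 0.00411 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 2 libraries per cell type). Lrrc3 (log2 9.45, SE 1.10), the metalloproteinase Adamts1 (9.31), the glutamate transporter Slc1a3 (8.30) and Tspan7 (8.39) were higher by a similar amount. Ly6c2, the surface marker of classical monocytes (chromosome 15, 75108158 to 75111970, minus strand), was lower at -7.24 (SE 1.12, adjusted p 0.00873 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The proteoglycan Vcan (-7.71) and the granule genes Camp (-9.002), Wfdc21 (-8.10) and Cd177 (-8.88) were lower as well. In wild-type and mutant monocytes Camp stood at 72.7 and 1817 CPM, Wfdc21 at 30.9 and 931 CPM, and Cd177 at 390 and 241 CPM. Reads from other blood cells in the monocyte sort, weighed below for the mutant, could add to these differences.

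Over all genes, 6 of 14 microglia markers passed as higher in intravascular macrophages than in monocytes, and 12 adjusted over the list alone. Of classical monocyte markers 3 of 14 passed as lower (12 adjusted over the list alone), of neutrophil markers 5 of 14 (10 adjusted over the list alone) and of erythroid markers 1 of 7 (4 adjusted over the list alone). Classical monocyte markers were still read in intravascular macrophages, where they summed to 5257 CPM in the wild type and 13981 CPM in the mutant. Patrolling monocyte markers gave 1 of 14 higher, with 3 higher and 1 lower adjusted over the list alone. No T and NK cell marker passed, while these genes differed between the wild-type and mutant intravascular macrophages as given above. In total 87 of 17023 genes changed, 46 higher and 41 lower. The count rose to 2126 (937 higher, 1189 lower) without the wild-type and to 5089 (1771 higher, 3318 lower) without the mutant intravascular macrophage library, and fell to 58 (18 higher, 40 lower) without the wild-type monocyte library. DESeq2's Wald test gave 988 and the fit without genotype 25.

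Genes of microglia were higher in microglia than in monocytes, and genes of classical and patrolling monocytes lower. Sall1 was higher at a log2 fold change of 11.32 (SE 1.20, adjusted p 0.000269 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and P2ry12, the ADP receptor of microglia, and Tmem119 at 8.94 and 8.86. Sall3, a relative of Sall1, stood at 12.24. Mymk, Eva1a, Adamts16, Chst8 and Nr3c2 had no count in either monocyte library and were at least 682-fold, 648-fold, 505-fold, 477-fold and 264-fold higher in microglia. Ly6c2 was lower at -12.89 (SE 1.39) and Ace, the angiotensin-converting enzyme of patrolling monocytes, at -10.02. The granzyme Gzma and the fatty acid carrier Fabp4 had 0 counts in both microglia libraries and were at least 1761-fold and 801-fold lower, and the granule genes Ngp (-13.48), Mmp8 (-14.08) and Cd177 (-13.88) followed. Reads from other blood cells in the monocyte sort could add to the differences of the granzyme and granule genes.

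As to groups, 12 of 14 microglia markers were higher in microglia than in monocytes (13 adjusted over the list alone), and 13 of 14 classical (14 adjusted over the list alone) and 11 of 14 patrolling monocyte markers (12 adjusted over the list alone) were lower. Neutrophil markers gave 10 of 14 lower (12 adjusted over the list alone), oxidative phosphorylation genes 10 of 30 (14 adjusted over the list alone), interferon response genes 5 of 29 (10 adjusted over the list alone), and adhesion and migration receptors 3 higher and 7 lower of 25 (8 and 10 adjusted over the list alone). Of 17023 genes, 300 were higher and 549 lower. The total of 849 became 5046 without the wild-type and 5142 without the mutant intravascular macrophages, which this comparison does not use except for the spread, and 382 without the mutant monocyte library.

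Intravascular macrophages differed from microglia by genes of patrolling monocytes. Ace (chromosome 11, 105967945 to 105989964, plus strand) was at 148 and 237 CPM in wild-type and mutant intravascular macrophages and at 0.0437 and 0.215 CPM in microglia, a log2 fold change of 10.57 (SE 1.24, adjusted p 0.00140 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). S1pr5 (11.08), Trem1, an amplifier of inflammation in myeloid cells (11.36), Atp8b4 (10.50), Ccdc88c (10.67) and the lymphoid transcription factor Ikzf3 (11.39) were also higher. Cdh1 (E-cadherin) and Fabp4 had 0 counts in both microglia libraries and were at least 732-fold and 518-fold higher. The genes lower in intravascular macrophages included Gpr84 (-4.34, SE 0.82), Upk1b (-4.09), Gem (-4.01), Ecscr (-3.69) and Tmem100 (-3.37), all higher in microglia of both genotypes.

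Of patrolling monocyte markers, 10 of 14 passed as higher in intravascular macrophages than in microglia (11 adjusted over the list alone), and of classical monocyte markers 7 of 14 (12 adjusted over the list alone). Adhesion and migration receptors gave 7 of 25 (10 adjusted over the list alone, with 3 lower). No microglia marker passed over all genes, with 11 lower adjusted over the list alone. Sall1 stood at -2.50 and P2ry12 at -3.73. In the simulation at a dispersion of 0.8, this comparison recovered 0 of 100 genes changed by 16-fold. Markers that did not pass are therefore not shown to be alike in both cell types. The T and NK cell list gave 0 over all genes and 14 higher adjusted over the list alone, on reads nearly all from the wild-type library. In total 213 genes were higher and 7 lower. The count of 220 became 716 without the wild-type and 5745 without the mutant intravascular macrophages, and 344 without the mutant microglia. Without the mutant intravascular macrophages most calls were lower (2144 higher and 3601 lower), and without the mutant microglia 259 were higher and 85 lower; limma on log2(TPM + 1) gave 85.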

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

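The tests in this part were chosen only after the results they bear on had been seen, and their bounds were set with the list counts already known, except the test of the heat shock genes, which was written before its result. Each result in the next paragraph was picked out because it stood in opposite directions in different cell types, and the patterns weighed after it were chosen once their values had been seen; the differences between cell types were not tested, since each rests on 1 library per genotype.

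The T and NK cell markers had a median log2 ratio of 1.79 in monocytes and -10.46 in intravascular macrophages. The metalloproteinases and their inhibitors stood at 3.52 in monocytes, 1.96 in intravascular macrophages and -1.08 in microglia. Interferon response genes were at -0.40 in monocytes, 1.64 in intravascular macrophages and 1.74 in microglia. Immediate early genes were at -0.26 in monocytes and 2.03 in microglia, and TGF-beta and microglia identity regulators at 0.87 in intravascular macrophages and -0.87 in microglia. Among single genes, Ifit3b was at -3.20 in monocytes and 2.64 in intravascular macrophages, and Irf4 at -2.89 and 4.45. Cd3d was at 2.93 and -11.45, Nkg7 at 2.94 and -11.37, and Cd3g at 3.65 and -11.01, in the same order. Gadd45b stood at 2.07 in monocytes, -2.48 in intravascular macrophages and 5.63 in microglia.

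Wild-type intravascular macrophages carried T and NK cell genes and lacked others. All 14 of the 14 marker genes reached 10 CPM there, led by Nkg7 at 1328 CPM, Cd3g at 481 and Cd3d at 424, against at most 6 in any other library and 0 in the mutant intravascular macrophages, so reads from T or NK cells in the sort are a candidate source; the gate that would remove them is not given in the sources used here. Another 72 genes at 10 CPM or more in each of the other 5 libraries had 3 counts or fewer in this one, where no other library lacked any. Transcripts lost at low input or low library complexity could account for this. Genes named above as higher in mutant intravascular macrophages on few wild-type counts are open to the same explanation. A difference between genotypes in the macrophages themselves stays open, because 1 library per genotype cannot separate it from other cells in the sort.

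In mutant microglia, only 28.2% of the single genes past the size rule kept their direction past it after the correction for transcript length and GC content, so length bias between the libraries may account for most of those calls. The oxidative phosphorylation list fell to percentile 58.9 (median 0.34) after the correction and is open to the same explanation. The tables argue against that bias as the whole cause for the immediate early genes, which stayed at percentile 100 with a corrected median of 2.27, and for the NF-kB and inflammatory genes, also at 100 with 1.78. Handling of the cells before lysis stays open for the immediate early genes: of 4 heat shock genes, 1 was at least 2-fold higher after correction (Dnajb1, 1.52), 1 was lower (Hspa1b, -1.29), and Hspa1a (0.82) and Hspb1 (-0.41) lay between. Whether handling also raised the NF-kB and inflammatory genes or the secretory factors of senescent cells was not tested. The genotype remains a further open explanation, untested with 1 library each.

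Granulocyte and erythroid genes were higher in mutant monocytes. Thinning the libraries to equal counts cannot decide whether the difference in depth was their cause, because it leaves the expected ratio of a gene nearly unchanged. It shows only that counting error at the lower depth did not remove the differences. Of 25 members of the neutrophil, immature granulocyte and erythroid lists at least 2-fold higher, 25 stayed so after thinning. Their medians were then 4.44, 3.70 and 5.60. A fall in the share of monocytes stays open. The dendritic cell markers stood at percentile 0.15 and not higher like the others. They cannot decide it, because added cells without dendritic cell genes would lower these markers too. Reads from other blood cells in the sort could account for the neutrophil genes, of which 12 of 14 were at least 2-fold higher (S100a9 at 23417 CPM and S100a8 at 22567), and for the erythroid genes, of which 7 of 8 were (Hba-a1 at 4547 CPM). The list members Csf3r and Ly6g, chosen after their values were seen, stood at 89.9 and 2.195 CPM in the mutant and at 169 and 0.169 CPM in the wild type, in that order; single genes picked in this way do not exclude that source. Expression of these genes by mutant monocytes stays open, and the gate is not given in the sources used here. Whether reads from other blood cells also raised the metalloproteinase, secretory factor and cell cycle lists in mutant monocytes was not tested.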

How the results depend on the processing

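The correction for transcript length and GC content, the random lists matched on length, the thinning, the sets without some genes or cell types and the counts of list members past the cell type tests were chosen after seeing the data; the other alternatives were planned. Except where a sentence below gives it from the construction (a looser or stricter threshold, fewer genes or fewer libraries), the cause of a change was not tested.

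With a looser level of 1 CPM, genes past the size rule numbered 1710.0 in monocytes, 5724 in intravascular macrophages and 1365 in microglia, and 52 were shared by all 3; at 50 CPM they were 326, 864, 313 and 7. At a log2 ratio of 1 they were 1925, 5334, 4689 and 144, and at 3 they were 248, 1743, 93 and 5. Library size alone gave 1524 in microglia and 10 shared genes, TPM 335 in monocytes and 10 shared, and the length and GC correction 346 in microglia and 11 shared. Monocytes and microglia alone shared 61. DESeq2 size factors and prior counts of 0.5 and 10 kept the counts of the 3 cell types and of the shared genes within 1.5 times. Thinning, run for the counts of the 3 cell types and not for the shared genes, kept them within 1.5 times too.

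Among lists that stood apart, the medians that turned sign were those of NF-kB genes (-0.10), lysosome genes (-0.11) and unfolded protein response genes (-0.16) in monocytes on TPM, and of TGF-beta regulators in microglia after the correction (0.090). No list that stood apart moved to the opposite side in any of the 7 settings; between 19 and 23 of 23 kept their side in monocytes, 15 and 16 of 16 in intravascular macrophages, and 10 and 13 of 13 in microglia. Lists that stood apart only under an alternative were, with a mean of at least 10 CPM required, endothelial markers and TGF-beta regulators in monocytes and immature granulocyte markers in intravascular macrophages, and with DESeq2 size factors dendritic cell and neuron markers in microglia, beside those named above for the correction and TPM. Against random lists matched on length, they were dendritic cell markers (percentile 97.6), cell cycle genes (99.4), lysosome genes (99.4) and, as lower, B cell markers (0.45) in microglia, beside those named above.

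Genes past the test of intravascular macrophages against monocytes (87) numbered 988 with DESeq2's Wald test, 429 with no filter on low counts, 25 with no genotype block and 296 with the 4 libraries compared. For microglia against monocytes (849) these were 2616, 1446, 538 and 5207, and limma on TPM gave 559. For intravascular macrophages against microglia (220) they were 889 with the Wald test, 518 with no filter and 115 with no block, and limma on TPM gave 85. No gene past a test turned its sign under these settings, but not all calls were kept. Limma on TPM kept 34 of 87, 449 of 849 and 76 of 220 calls in the same direction. The Wald test kept 87, 842 and 220, in the same order of comparisons.

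Members of the lists past these tests were 23, 138 and 43 in that order of comparisons. The Wald test gave 125, 235 and 128, no block 8, 91 and 23, and no filter 86 for the first and 92 for the third. The 4 libraries alone gave 72 and 324 for the first and second, and limma on TPM 24 for the third.

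Leaving out 1 library gave 58 to 5089 genes for intravascular macrophages against monocytes, 382 to 5142 for microglia against monocytes and 158 to 5745 for intravascular macrophages against microglia, and 19 to 252, 80 to 331 and 40 to 274 list members. In each, leaving out an intravascular macrophage library raised the count most: 2126, 5046 and 716 without the wild type, 5089, 5142 and 5745 without the mutant. Without the wild-type microglia the first comparison gave 310.0 genes and the second 463; without the mutant microglia the first gave 330.0 and the third 344. Without wild-type or mutant monocytes the second gave 487 and 382, and without the wild-type monocytes the first gave 58. List members moved with the same libraries: without the wild-type intravascular macrophages they were 172, 328 and 122, and without the mutant ones 252, 331 and 274. They were 74 for the first without either microglia library, 80 for the second without the mutant monocytes and 70 for the third without the mutant microglia. Where the left-out library leaves a cell type with 1 sample, that sample is assumed to vary like the other groups.

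Genotypes could not be compared in pairs, because each group holds 1 library. In the cell type comparisons the genotype, which pairs libraries across cell types, is already a block in the main design. Depth limits genes near the floor of 3 counts, between 0.0351 and 0.127 CPM in these libraries, and ratios on 1 to 3 counts, whose intervals span orders of magnitude.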

Other observations

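The genes and ratios in this part were chosen after the values were seen. Beyond Prg2, the mutant monocyte library held further genes of eosinophils, and whether monocytes or other cells in the sort made them was not tested. Prg3 stood at 14.3 CPM against 0 counts (at least 113-fold higher), the eotaxin receptor Ccr3 at 20.6 CPM against 0 (at least 162-fold), the lipoxygenase Alox15 at 18.1 CPM (at least 142-fold) and the ribonuclease Ear6 at 12.1 CPM (at least 95.3-fold). Epx, the eosinophil peroxidase, was 252-fold higher (44.9 to 9964, on 1 wild-type count). Il5ra, the interleukin 5 receptor of eosinophils, had 11 counts in the mutant and 0 in the wild type. Saa3, an acute phase gene, was also far apart, at 1583 CPM against 3.52 (450.3-fold, 363 to 565). So was Mt2, a metallothionein, at 352 CPM against 0.169 (2078-fold, 812 to 7629). Ccl24, an eosinophil chemoattractant, was 367-fold higher (226 to 643), and Pdpn, a surface glycoprotein of inflammatory macrophages, at 29.8 CPM against 0, at least 235-fold higher.

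Microglia markers in intravascular macrophages stood at a median of 12.97% of their level in microglia in the mutant libraries, with a range over genes of 8.90% to 164%. In the wild-type libraries the median was 7.61%, with a range of 0.185% to 17.7%. These shares do not show whether the reads came from the macrophages themselves or from microglia in the sort, in either genotype. The 72 genes missing from wild-type intravascular macrophages included widely expressed ones: Aifm1, a mitochondrial flavoprotein, had 1 count there and 560.0 to 2233 in the others, and Ddx1, an RNA helicase, 3 counts and 828 to 6404.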
